A study of Mus musculus with 23 samples.

How the data were processed

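Expression was measured on 23 oligonucleotide arrays (Affymetrix MOE430A), each hybridised with RNA from whole back skin of female mice of the CD-1 stock. CD-1 is an outbred stock. The skin had been painted with the solvent DMSO or with 4 mg of AG825, a tyrphostin inhibitor of the receptor tyrosine kinase Erbb2, 2 h before exposure to 10 kJ/m2 of ultraviolet light (UV) or a sham exposure. Skin was taken 6 h or 24 h after UV, and 6 h after sham, so that the 24 h groups have no sham skin of the same age.

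The deposited files hold 3 summaries of the same arrays. The deposited table used for every main value is in log2 units and was made with RMA, per the submitters' processing notes, which state no version; it covers 19645 probe sets on 23 arrays. The other tables hold signal on a linear scale, per the file headers, with a detection call for each probe set. One was made with dChip for 23 arrays, and the other with the GCOS software for 22 arrays, without DMSO 6 h replicate G. Both cover 22690 probe sets, of which 64 are controls and 2981 cross-hybridising probe sets are absent from the log2 table. The unit of each table was checked on its values: the log2 table has nearly the same distribution on every array, and the GCOS signal had not been scaled between arrays. No array was left out, and every column that holds a value per sample was used. The probe sets of the log2 table were paired with gene symbols through the platform table supplied with the series: 17825 named 1 gene, 445 named several and 1375 named none, which gave 12106 genes. Signal over background limits what arrays can show; a gene called absent on all arrays of the dimmer group is given as a fold of at least the value stated, and the number of arrays limits the precision of every value.

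A model with 1 mean for each of the 6 groups was fitted to the log2 values of all probe sets (limma 3.58.1 in R 4.3.3, eBayes, 20.75 degrees of freedom in all). There were 9 planned comparisons, each two-sided: UV against sham at 6 h and at 24 h in each drug group, AG825 against DMSO after sham, at 6 h and at 24 h, and the interaction of drug and UV at each time. P-values were adjusted over all probe sets of a comparison by the Benjamini-Hochberg method, and a probe set passed at an adjusted p of 0.05. Adjusted p-values given for single genes come from this limma model, and errors of log2 differences are its standard errors (SE). The labels do not state whether replicates are separate animals, so p-values measure the spread between these samples. Replicate letters were not used as pairs, since the labels do not say what they mark.

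For 26 gene lists fixed before the data were examined, with 387 of 433 listed genes measured, each gene was represented by its probe set with the highest mean over all arrays. Each list was tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 26 lists, and members were counted past the threshold over all probe sets and adjusted over the list alone. The lists cover p53 target genes, inflammatory cytokines and prostaglandin synthesis, stress keratins and alarmins, epidermal differentiation, mitotic cell cycle, G1/S and DNA replication, ERBB receptors with their ligands and regulators, immediate early genes and MAPK feedback, the NRF2 oxidative stress response, aryl hydrocarbon receptor targets, heat shock and unfolded protein response, interferon response, cholesterol synthesis, sebaceous gland and fatty acid synthesis, matrix proteases and wound remodelling, and the circadian clock. Others mark tissue make-up: neutrophils, macrophages and general leukocytes, Langerhans and T cells, mast cells, hair shaft and anagen follicle, melanocytes, adipocytes, skeletal muscle, fibroblasts with structural matrix, and endothelium. A list score is the mean of the members' log2 values on an array after centring each gene over the arrays; list scores of the groups were also compared by an exact permutation of the array labels, a test added after the data had been seen.

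The drug effect along the UV response was the mean AG825 minus DMSO difference, among the UV arrays of 1 time, over the 200 genes with the highest and the 200 with the lowest moderated statistic of all UV arrays against all sham arrays. Falling genes counted with reversed sign, so that a negative value lies towards sham. Because both drug groups were pooled to choose these genes, the choice did not use the drug labels. It was tested by an exact permutation of the drug labels over those arrays (35 splits, two-sided).

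Named genes followed a rule fixed in advance: the 10 largest rises and the 10 largest falls that passed, naming a single gene and with no overlap of arrays between groups; up to 4 members with the smallest adjusted p of each list described; Erbb2, Egfr, Erbb3 and Erbb4; and Ptgs2, Il1b, Cdkn1a, Mki67, Krt6a and Cyp1a1. The text prints part of these.

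The steps were tested on simulated data in which 200 of 19645 probe sets were shifted. For AG825 against DMSO at 6 h, 46.3% of shifts of 0.5, 85.1% of shifts of 1 and 100% of shifts of 2 on the log2 scale were called, and 3.75% of calls were unshifted probe sets. For the comparison at 24 h the shares were 37.3%, 91.0% and 98.5%. The shifted probe sets were drawn at random and the noise was independent between probe sets. The shares therefore do not hold for genes that vary together or vary widely between arrays. Hair genes, for example, had a mean difference of 1.95 between the drugs at 6 h with 0 of 18 called over all probe sets.

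Alternatives fixed in advance were the dChip signal, the GCOS signal scaled here to 1 trimmed mean (2% trimmed at each end) with a pseudocount of 16 or of 1, a filter on the dimmest 33.3% of probe sets (13097 left), a filter on probe sets present on at least 3 arrays of a group (14150 left), median centring, a variance trend with robust moderation, array weights, a fit of only the groups compared, the replicate letter as a block, 100 or 500 genes per direction for the drug effect along the UV response, the median probe set of a gene, and each array left out in turn. Chosen after the data had been seen were the hair list score as a covariate, the percent of present calls as a covariate, leaving out the 3 arrays with the lowest percent of present calls, the permutation of list scores, and the comparisons of 24 h with 6 h within each drug group. Random steps used seed 1.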

Results

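Whole dorsal skin of female CD-1 mice was profiled on 23 arrays in a layout of drug by irradiation. Skin painted with the solvent DMSO gave 4 arrays after sham exposure, 4 at 6 h after UV and 4 at 24 h after UV. Skin painted with AG825, an inhibitor of the kinase activity of Erbb2, gave 4 arrays after sham, 4 at 6 h and 3 at 24 h. Each array reports 19645 probe sets in log2 units. The percent of probe sets called present was 68.6 ± 2.45 (SD, n = 4) in DMSO sham, 65.0 ± 3.0 at 6 h and 69.1 ± 2.79 at 24 h in DMSO skin; in AG825 skin it was 69.2 ± 1.30 after sham, 66.6 ± 2.44 at 6 h (n = 4) and 71.0 ± 0.675 at 24 h (n = 3). The lowest percentages were 62.3 on DMSO 6 h replicate E, 64.1 on AG825 6 h replicate A and 64.2 on DMSO 6 h replicate F. Arrays of the same group correlated across probe sets at r between 0.957 and 0.992. The labels do not state whether replicates are separate animals, so p-values measure the spread between these samples.

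The question of what UV does to DMSO skin by 6 h was addressed with 4 irradiated and 4 sham arrays. Genes of acute inflammation rose most. Chil3, a chitinase-like protein of macrophages, was at least 34.7-fold higher, and the pentraxin Ptx3 rose by 4.53 ± 0.38 (log2 difference ± SE here and for every gene that follows). The neutrophil-attracting chemokines Cxcl2, Cxcl1 and Cxcl5 rose by 4.49 ± 0.49, 4.22 ± 0.35 and 4.16 ± 0.31, the cytokine Il6 by 3.67 ± 0.45, and Cd14, a lipopolysaccharide co-receptor of myeloid cells, by 3.95 ± 0.29. The deepest falls were in hair keratins and their partners: Krt25 and Tchh, both of the inner root sheath, fell, with differences of -4.69 ± 0.86 and -4.11 ± 0.93, as did the hair shaft keratins Krt33a and Krt31, with -4.59 ± 1.09 and -4.25 ± 0.96. In all, 3623 of 19645 probe sets passed, 1527 higher and 2096 lower (1641 and 1445 with the dChip signal). Of the 3623, 885 changed by at least 2-fold, 521 higher and 364 lower.

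Of 23 measured inflammatory cytokines and prostaglandin genes, 18 rose (21 adjusted over the list alone), with a camera adjusted p of 1.19e-18 and adjusted p = 0.018 with an estimated correlation. Il1b, a central inflammatory cytokine, rose by 3.23 ± 0.30 (adjusted p = 6.56e-07), and Ptgs2, the inducible cyclooxygenase, by 2.44 ± 0.31 (adjusted p = 2.13e-05). Leukocyte markers rose as well: 16 of 17 macrophage and general leukocyte genes (17 adjusted over the list alone), among them the Fc receptor Fcgr3 by 2.95 ± 0.35 and the signalling adaptor Tyrobp by 2.48 ± 0.31. The list had a camera adjusted p of 3.28e-16 and adjusted p = 0.0776 with an estimated correlation. Of 11 neutrophil genes, 8 rose (9 adjusted over the list alone), with Fpr2, a receptor for bacterial peptides, up by 3.55 ± 0.22 and Clec4e by 3.51 ± 0.30 (camera adjusted p = 2.93e-08, adjusted p = 0.0776 with an estimated correlation). Among 17 interferon-responsive genes 16 rose (17 adjusted over the list alone). The T cell-attracting chemokines Cxcl9 and Cxcl10 rose, Cxcl9 to at least 10.1-fold, and the antiviral gene Oasl2 rose by 2.91 ± 0.34 (camera adjusted p = 1.62e-12, adjusted p = 0.0881 with an estimated correlation). Of 16 matrix protease and wound genes 11 rose (11 rose and 1 fell adjusted over the list alone). Timp1, an inhibitor of metalloproteases, rose by 2.31 ± 0.28 and the stromelysin Mmp3 by 1.91 ± 0.23 (camera adjusted p = 1.96e-06, adjusted p = 0.0469 with an estimated correlation). The immediate early list had 8 members that rose and 1 that fell of 19 (9 and 1 adjusted over the list alone). The transcription factors Fos and Atf3 rose by 1.57 ± 0.21 and 1.30 ± 0.20 (camera adjusted p = 0.000222, adjusted p = 0.0776 with an estimated correlation). Endothelial genes rose in 7 of 10 members, Cdh5, the cadherin of endothelial junctions, by 1.36 ± 0.24 (camera adjusted p = 4.89e-05, adjusted p = 0.123 with an estimated correlation).

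Hair, pigment and proliferation genes were lower in the same 4 irradiated arrays. Of 18 hair shaft and anagen follicle genes 17 fell (18 adjusted over the list alone), with a mean difference of -3.17 ± 0.64 in list score. Hoxc13, a regulator of hair keratin genes, fell by 2.89 ± 0.38 (list camera adjusted p = 1.62e-12, adjusted p = 0.103 with an estimated correlation). The hair scores were uneven among the irradiated DMSO arrays, from -3.18 on replicate F to -0.55 on replicate C, against a mean of 1.17 ± 0.29 (SD) after sham. Of 8 melanocyte genes 7 fell, among them the pigment genes Pmel (-2.27 ± 0.35) and Tyr (-2.06 ± 0.32) (camera adjusted p = 1.96e-06, adjusted p = 0.103 with an estimated correlation). Mitotic genes fell in 19 of 20 members (20 adjusted over the list alone), with Mki67, a proliferation marker, down by -1.84 ± 0.31 (adjusted p = 0.000332) and the cyclin Ccnb2 by -1.28 ± 0.21. The mitotic list had a camera adjusted p of 1.69e-13 and adjusted p = 0.103 with an estimated correlation. Of 20 genes of G1/S and DNA replication 14 fell (18 adjusted over the list alone), such as the helicase subunits Mcm2 by -1.27 ± 0.18 and Mcm5 by -1.09 (camera adjusted p = 1.49e-08, adjusted p = 0.0797 with an estimated correlation). Cholesterol synthesis genes fell in 8 of 13 members (9 adjusted over the list alone), with Hmgcs1 down by -1.09 ± 0.21 (camera adjusted p = 2.93e-05, adjusted p = 0.121 with an estimated correlation).

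The mRNA of Erbb2, the receptor that AG825 targets, fell in whole skin after UV, by 0.70 ± 0.15 (adjusted p = 0.00193). Receptor protein was not measured on these arrays. Erbb3, a partner of Erbb2, fell by 0.96 ± 0.21 (adjusted p = 0.00315), although another probe set for Erbb3 did not pass. Egfr differed by -0.14 ± 0.13 (adjusted p = 0.501) and Erbb4, called absent on all arrays, by 0.12 ± 0.09 (adjusted p = 0.403). Of the 12 ERBB list members 2 rose and 2 fell, with a mean of 0.22 (camera adjusted p = 0.401). The EGFR ligand Epgn rose by 2.33 ± 0.21 and Errfi1, a feedback inhibitor of ERBB kinases, by 1.14 ± 0.21. Of 21 p53 target genes 4 rose and 1 fell (6 and 1 adjusted over the list alone), with a mean of 0.16, a median of -0.02 and a camera adjusted p of 0.248. Pmaip1, which encodes the pro-apoptotic protein Noxa, rose by 2.02 ± 0.33 (adjusted p = 0.000255), while Cdkn1a, the cell cycle inhibitor p21, differed by 0.36 ± 0.17 (adjusted p = 0.149). Of 14 NRF2 genes 2 rose and 2 fell (3 and 3 adjusted over the list alone; mean 0.00, camera adjusted p = 0.966); the haem oxygenase Hmox1 rose by 1.10 ± 0.28 and the glutathione synthesis gene Gclc fell by 1.46 ± 0.23. Krt6a, a keratin of stressed epidermis, differed by 0.32 ± 0.43 (adjusted p = 0.648), and Cyp1a1, a target of the aryl hydrocarbon receptor, by 0.03 ± 0.21 (adjusted p = 0.946).

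The other lists moved less evenly at 6 h. Skeletal muscle genes rose in 5 of 16 members (10 adjusted over the list alone), with myosin Myh2 up by 2.12 ± 0.45 (camera adjusted p = 0.000232, adjusted p = 0.384 with an estimated correlation), and fibroblast matrix genes in 4 of 16 (6 adjusted over the list alone), with the collagen cross-linking enzyme Lox up by 1.78 ± 0.31 (camera adjusted p = 0.000392, adjusted p = 0.39 with an estimated correlation). Mast cell genes rose in 4 of 8 members (camera adjusted p = 0.0244, adjusted p = 0.236 with an estimated correlation), a call lost without DMSO 6 h replicate C (adjusted p = 0.0569). Stress keratins and alarmins rose in 3 of 14 members, with the antimicrobial protein Lcn2 up by 3.13 ± 0.65 (camera adjusted p = 0.0312, adjusted p = 0.55 with an estimated correlation). That call was lost without DMSO sham replicate A (adjusted p = 0.34), DMSO 6 h replicate C (0.214) or DMSO 6 h replicate G (0.0768). Without DMSO sham replicate A the lists of epidermal differentiation (2 of 18 fell, mean -0.34, camera adjusted p = 0.192) and of sebaceous and fatty acid synthesis genes (4 of 13 fell, mean -0.28, camera adjusted p = 0.0628) passed instead, at 0.00493 and 0.0338. Camera made no call for aryl hydrocarbon receptor targets (1 of 7 rose, 0.318), Langerhans and T cells (2 of 14 rose, 0.116), adipocytes (0 of 12, mean 0.38, 0.119), heat shock and unfolded protein genes (2 rose and 2 fell of 15, mean -0.01, median 0.15, 0.401) or the circadian clock (1 rose and 1 fell of 15, mean 0.03, median -0.00, 0.966), where the last value in each bracket is the camera adjusted p. By exact permutation of list scores 20 of the 26 lists differed (p = 0.0286 each, the smallest that 70 labelings allow, adjusted p = 0.0371). At this smallest p, passing after adjustment depends only on how many lists reach it. These 20 include 5 that camera did not call: aryl hydrocarbon receptor targets, Langerhans and T cells, adipocytes, sebaceous and fatty acid synthesis genes, and the p53 targets. Camera called 16 lists at the preset correlation and 2 with an estimated one.

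At 6 h, 18.7% of probe sets had no overlap between the irradiated and sham arrays of DMSO skin, where chance gives 2.86%. The count of 3623 dropped to 1868 without the 3 arrays of lowest percent present, to 2068 with percent present as a covariate and to 305 with the hair score as a covariate. With the GCOS signal and a pseudocount of 16, the median of all probe sets shifted by -0.11 and with a pseudocount of 1 by -0.15 for this comparison, below the size of every list mean given above as risen or fallen.

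**Figure D1:**
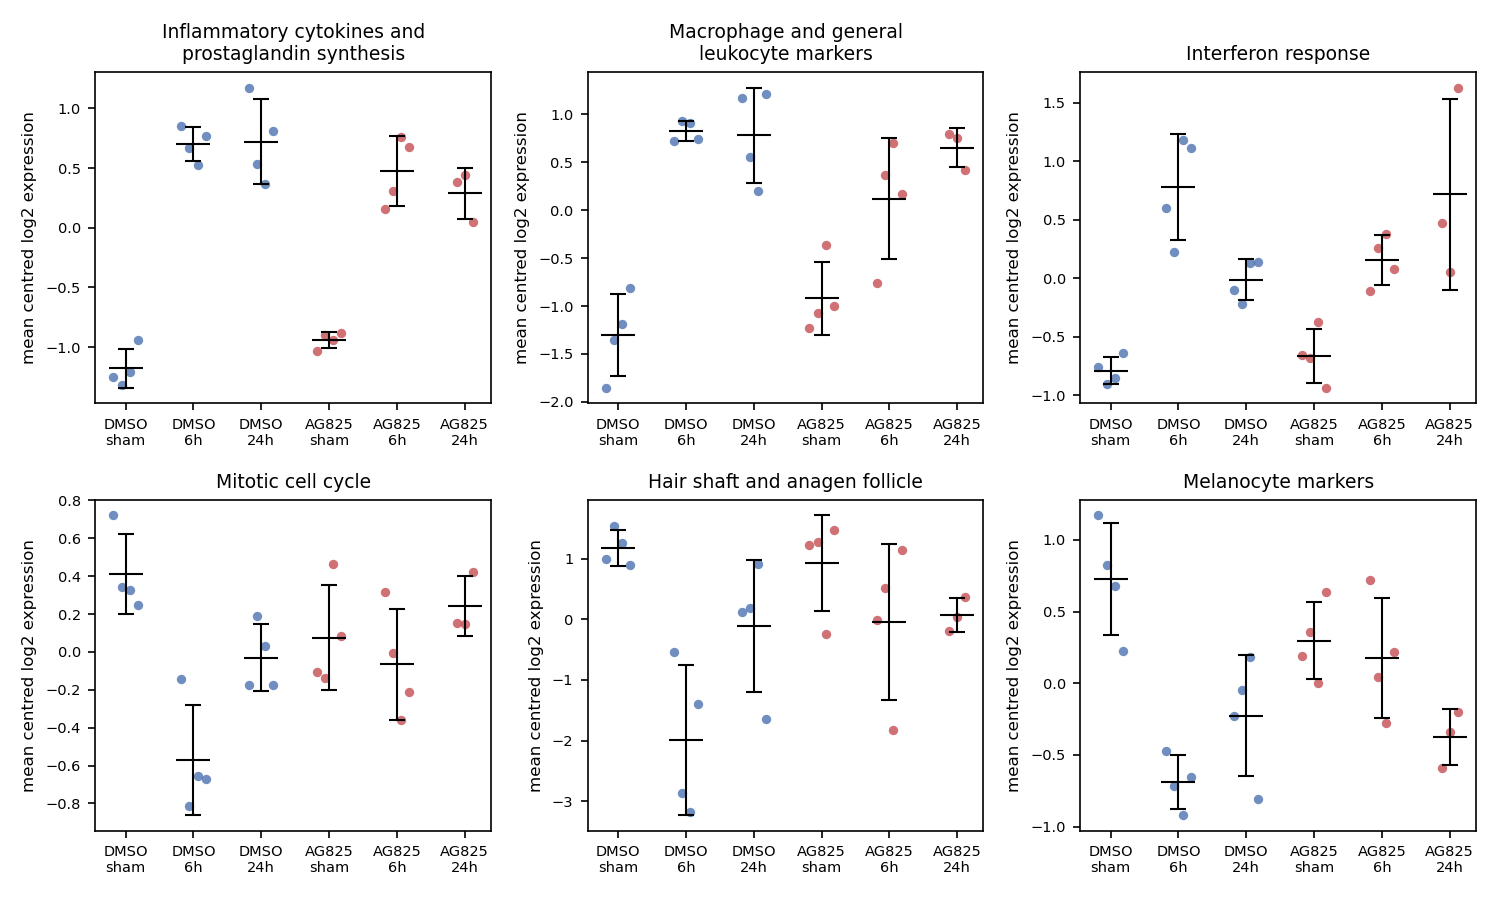
List score (mean centred log2 expression) of 6 gene lists on each array, by group (DMSO in blue, AG825 in red; points are arrays, black bars the mean ± SD). The macrophage score rose from -1.30 after sham to 0.83 at 6 h in DMSO skin, and the hair score of DMSO skin at 6 h has a mean of -2.00 with an SD of 1.24.

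At 24 h, 4 irradiated DMSO arrays were compared with the same 4 sham arrays, which had been taken at 6 h, so time since treatment was not matched. Inflammatory genes were again the most increased, now with the chemokines Cxcl2 and Cxcl5 up by 5.36 ± 0.49 and 5.33 ± 0.31, the acute-phase gene Saa3 by 5.09 ± 0.64, Il1b by 4.10 ± 0.30 and Ptgs2 by 2.69 ± 0.31. Genes of the cornified layer were among the deepest falls: the late envelope genes Lce1a1, Lce1a2 and Lce1b fell, with differences of -2.19 ± 0.44, -1.76 ± 0.29 and -1.70 ± 0.36. So did the metallothionein Mt4 (-2.46 ± 0.57) and the fatty acid elongase Elovl6 (-1.94 ± 0.33). In all, 1714 probe sets passed, 961 higher and 753 lower (935 and 331 with the dChip signal, 767 and 411 with the GCOS signal at a pseudocount of 16, 679 and 296 at 1), and 517 of the 1714 changed by at least 2-fold (398 higher and 119 lower).

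Of 23 cytokine and prostaglandin genes 15 rose (19 adjusted over the list alone; camera adjusted p = 4.92e-25, adjusted p = 0.00217 with an estimated correlation). Macrophage and general leukocyte genes rose in 16 of 17 members, Ms4a7 by 2.24 ± 0.29 and the leukocyte phosphatase Ptprc by 2.10 ± 0.28 (camera adjusted p = 7.77e-25, adjusted p = 0.0275 with an estimated correlation). Neutrophil genes rose in 6 of 11 members (8 adjusted over the list alone), with the growth factor receptor Csf3r up by 1.63 ± 0.26 (camera adjusted p = 7.53e-11, adjusted p = 0.0341 with an estimated correlation). Matrix protease and wound genes rose in 11 of 16, with the matrix protein Tnc up by 2.43 ± 0.25 and the gelatinase Mmp9 by 1.85 ± 0.20 (camera adjusted p = 7.68e-14, adjusted p = 0.00163 with an estimated correlation). Endothelial genes rose in 7 of 10 members (camera adjusted p = 5.86e-09, adjusted p = 0.0494 with an estimated correlation). Interferon-responsive genes rose in 5 of 17 (7 adjusted over the list alone), with Oasl2 up by 2.19 ± 0.34 (camera adjusted p = 6.15e-07, adjusted p = 0.24 with an estimated correlation). Immediate early genes had 6 members that rose and 1 that fell of 19 (camera adjusted p = 0.000253, adjusted p = 0.0697 with an estimated correlation). Stress keratins and alarmins rose in 3 of 14, with a mean of 1.17 (camera adjusted p = 0.000675, adjusted p = 0.382 with an estimated correlation), a call lost without DMSO sham replicate A (0.70, adjusted p = 0.0569). Fibroblast matrix genes rose in 1 of 16, with a mean of 0.44 (camera adjusted p = 0.000253, adjusted p = 0.382 with an estimated correlation) that was 0.26 without DMSO 24 h replicate E. Mast cell genes rose in 1 of 8, with a mean of 0.47 (camera adjusted p = 0.02, adjusted p = 0.265 with an estimated correlation), a call lost without DMSO 24 h replicate E (0.26, adjusted p = 0.0983).

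Epidermal differentiation genes fell in 8 of 18 members (9 adjusted over the list alone), among them Lor, which encodes loricrin, by -1.23 ± 0.21, although another probe set for Lor did not pass (camera adjusted p = 5.44e-06, adjusted p = 0.281 with an estimated correlation). Cholesterol synthesis genes fell in 8 of 13 (12 adjusted over the list alone), with Hmgcs1 down by -0.97 ± 0.21 (camera adjusted p = 3.26e-07, adjusted p = 0.0742 with an estimated correlation). Among sebaceous and fatty acid synthesis genes 4 fell and 1 rose of 13 (camera adjusted p = 0.000749, adjusted p = 0.121 with an estimated correlation). Melanocyte genes fell in 6 of 8 (camera adjusted p = 6.23e-06, adjusted p = 0.14 with an estimated correlation). Hair genes fell in 4 of 18, with a mean of -1.28 and Lef1, a Wnt pathway transcription factor of the follicle, down by -0.96 ± 0.15 (camera adjusted p = 2.37e-05, adjusted p = 0.343 with an estimated correlation). The hair mean was -0.77 without DMSO 24 h replicate E. Mitotic genes fell in 3 of 20, with a mean of -0.44 (camera adjusted p = 1.24e-05, adjusted p = 0.343 with an estimated correlation). Mki67 differed by -0.99 ± 0.31 (adjusted p = 0.0513, with 0.0398 without DMSO 24 h replicate B and 0.0474 without replicate C). Its value on DMSO sham replicate A, 10.9, lay above the others of that group, 9.99 to 10.1, which deepens this difference. No gene of the G1/S list passed. The list had a mean of -0.23, with 18 of 20 members negative (camera adjusted p = 0.0317, adjusted p = 0.441 with an estimated correlation). That call was lost without DMSO sham replicate A (-0.16, adjusted p = 0.146) or C (-0.23, 0.0515) or DMSO 24 h replicate E (-0.17, 0.19). Cd207, the Langerhans cell marker langerin, was at least 2.15-fold lower, one of 3 Langerhans and T cell genes that fell of 14 (mean -0.04, median 0.11, camera adjusted p = 0.838). Erbb2 fell by 0.67 ± 0.15 (adjusted p = 0.00506) and Erbb3 fell by 0.87 ± 0.21 (adjusted p = 0.0122), a call lost without DMSO 24 h replicate E (-0.64, adjusted p = 0.0608). Egfr differed by 0.03 (adjusted p = 0.956), Erbb4 by -0.03 (0.94), Cdkn1a by 0.12 (0.809), Krt6a by 0.93 ± 0.43 (0.219; 0.53 without DMSO sham replicate A) and Cyp1a1 by -0.66 ± 0.21 (0.0545). At 24 h, 14% of probe sets had no overlap between groups, where chance gives 2.86%. The count of 1714 became 975 without DMSO 24 h replicate E, 993 without DMSO 24 h replicate A and 1083 without DMSO sham replicate B, and 1133 with the hair score as a covariate. By exact permutation 11 lists had p = 0.0286, the smallest that 70 labelings allow. None passed after adjustment (lowest adjusted p = 0.0675). At the smallest p that outcome depends only on how many of the 26 lists reach it, so it decides nothing about single lists.

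**Figure D2:**
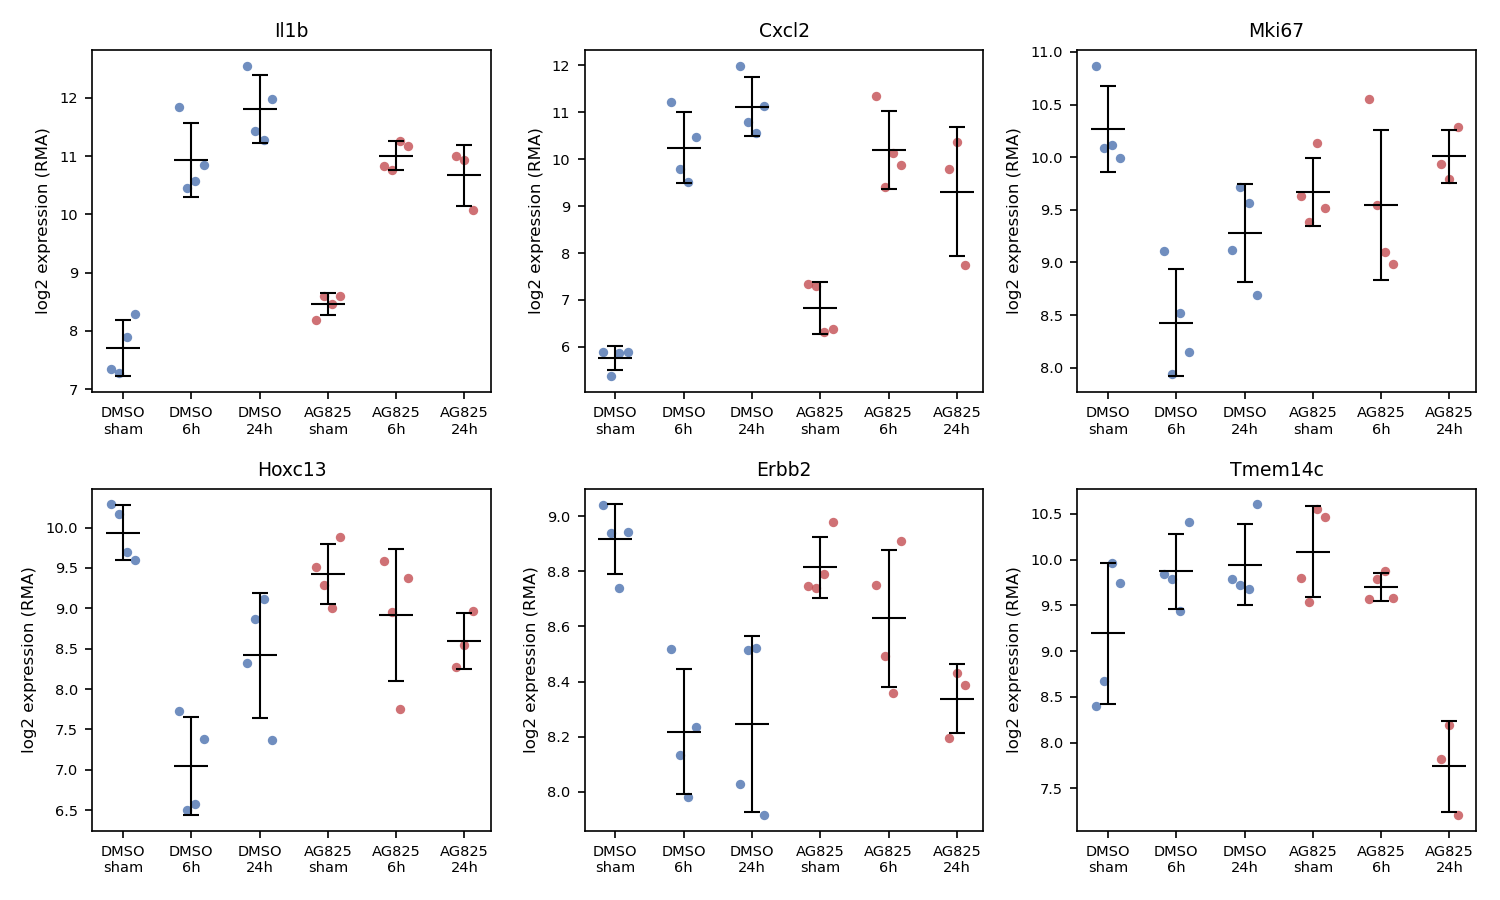
Log2 expression (RMA) of Il1b, Cxcl2, Mki67, Hoxc13, Erbb2 and Tmem14c on each array, by group (DMSO in blue, AG825 in red; points are arrays, black bars the mean ± SD). Il1b in DMSO skin was higher than sham by 3.23 at 6 h and by 4.10 at 24 h, and Erbb2 fell by 0.70 at 6 h.

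Whether AG825 alters unirradiated skin was asked with 4 AG825 and 4 DMSO sham arrays. Little separated them. Erbb2 differed by -0.10 ± 0.15, Egfr by -0.12 ± 0.13, Erbb3 by -0.00 ± 0.21 and Erbb4 by 0.03 ± 0.09. Ptgs2 differed by 0.31 ± 0.31, Il1b by 0.76 ± 0.30, Cdkn1a by -0.06 ± 0.17, Mki67 by -0.60 ± 0.31, Krt6a by 0.26 ± 0.43 and Cyp1a1 by -0.04 ± 0.21. The lowest adjusted p of any probe set was 0.879. Among listed genes only Slc45a2, a melanosome transporter, passed adjusted over the list alone, at -0.57 ± 0.18 (0.035). Camera at the preset correlation called 13 of the 26 lists. In the 4 with the lowest p, mitotic genes were lower by a mean of -0.34 (adjusted p = 2.48e-15) and melanocyte genes by -0.43 (1.11e-07), macrophage genes higher by 0.38 (3.23e-09) and cytokine genes by 0.24 (9.21e-06). None of the 26 lists passed with an estimated correlation (lowest adjusted p = 0.187 with an estimated correlation) or by exact permutation (lowest unadjusted p = 0.0857, lowest adjusted p = 0.594). The macrophage mean was 0.20 without either AG825 sham replicate D or DMSO sham replicate A, and the melanocyte mean was -0.28 without DMSO sham replicate A. Limma called 0 probe sets, with 193 (0.982%) at an unadjusted p under 0.05, and 0 under each alternative tried. The 95% interval of the difference lay within ±1 on the log2 scale for 97.4% of probe sets.

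AG825 and DMSO skin at 6 h after UV were compared with 4 arrays each, to ask whether the drug alters the irradiated skin. Hair, pigment and proliferation genes had higher values with AG825, and leukocyte genes lower values. Hoxc13 was 1.87 ± 0.38 higher (adjusted p = 0.235 over all probe sets, 0.00139 adjusted over the list alone), the pigment gene Pmel 1.67 ± 0.35 higher (0.235 and 0.000678) and Mki67 1.12 ± 0.31 higher (0.411 and 0.0134). The Mki67 difference leans on AG825 6 h replicate A, at 10.6 against 8.99 to 9.55 on the others of its group. Ptprc was lower, at -0.87 ± 0.28 (0.0436 adjusted over the list alone). Members that passed adjusted over the list alone numbered 14 of 18 for hair (mean 1.95), 10 of 20 for mitosis (mean 0.50), 6 of 20 for G1/S (mean 0.37), 5 of 8 for melanocytes (mean 0.87), 7 of 17 for macrophages (mean -0.70) and 0 of 17 for interferon (mean -0.63). Camera at the preset correlation called 15 of the 26 lists, and its adjusted p was 1.34e-17 for hair, 2.87e-14 for mitosis, 4.48e-10 for G1/S, 2.9e-07 for melanocytes, 5.33e-11 for macrophages and 4.91e-10 for interferon. None of the 15 calls held, with adjusted p = 0.179 with an estimated correlation for these 6 lists, the lowest of the 26. The macrophage mean was -0.41 without AG825 6 h replicate A. By exact permutation of list scores the melanocyte and macrophage lists had p = 0.0286, the smallest possible, and the hair list p = 0.0857. After adjustment the lowest was 0.248. That value follows from 3 lists at the smallest possible p, so it decides nothing about them.

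Erbb2 differed between the drugs by 0.41 ± 0.15 at 6 h (adjusted p = 0.506), Egfr by 0.09 ± 0.13 (0.951), Erbb3 by 0.39 ± 0.21 (0.755) and Erbb4 by -0.01 ± 0.09 (0.995). Ptgs2 differed by -0.41 ± 0.31 (0.862), Il1b by 0.07 ± 0.31 (0.987), Cdkn1a by 0.13 ± 0.17 (0.95), Krt6a by 0.09 ± 0.43 (0.989) and Cyp1a1 by -0.15 ± 0.21 (0.951). Limma called 0 probe sets, with 1415 (7.2%) at an unadjusted p under 0.05; the GCOS signal gave 2 with a pseudocount of 16 and 4 with 1, and the dChip signal 0. Without AG825 6 h replicate D the count was 21, without DMSO 6 h replicate C it was 2 and without DMSO 6 h replicate E it was 1. Arrays did not overlap for 2.04% of probe sets, where chance gives 2.86%.

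The interaction at 6 h asks whether the UV response itself differed between AG825 and DMSO skin. Members that passed adjusted over the list alone were 17 of 20 mitotic genes, 6 of 8 melanocyte genes, 12 of 17 macrophage genes, 8 of 18 hair genes and 0 of 23 cytokine genes. Camera called 16 of the 26 lists at the preset correlation and 0 with an estimated one (lowest adjusted p = 0.0924 with an estimated correlation). Mki67 had an interaction of 1.71 ± 0.44, Pmel of 2.09 ± 0.49 and Hoxc13 of 2.39 ± 0.54, each a smaller fall with AG825. High values on DMSO sham replicate A (10.9, others of its group 9.99 to 10.1) and AG825 6 h replicate A (10.6, others 8.99 to 9.55) both raise that of Mki67. Ptprc had an interaction of -1.24 ± 0.39 and Cd14 of -1.19 ± 0.41, each a smaller rise. The mitotic list had a mean of 0.84 ± 0.27 (camera adjusted p = 5.46e-20, adjusted p = 0.0924 with an estimated correlation; permutation p = 0.00776, adjusted 0.0672). The melanocyte list had a mean of 1.30 ± 0.33 (camera adjusted p = 2.77e-10, adjusted p = 0.0924 with an estimated correlation; permutation p = 0.00245, adjusted 0.0637). The macrophage list had a mean of -1.09 ± 0.43 (camera adjusted p = 1.64e-14, adjusted p = 0.121 with an estimated correlation; permutation p = 0.0159, adjusted 0.0828). The cytokine list had a mean of -0.47 ± 0.19 (camera adjusted p = 4.5e-06, adjusted p = 0.143 with an estimated correlation; permutation p = 0.022, adjusted 0.0876). Part of these list interactions lay in the sham arrays. The AG825 minus DMSO means there were -0.34 for mitotic, -0.43 for melanocyte, 0.38 for macrophage and 0.24 for cytokine genes. At 6 h after UV they were 0.50, 0.87, -0.70 and -0.23. For single genes the interaction was 0.52 ± 0.21 for Erbb2 (adjusted p = 0.688), 0.21 for Egfr (0.973), 0.39 for Erbb3 (0.957), -0.04 for Erbb4 (0.998), -0.72 ± 0.44 for Ptgs2 (0.912) and -0.68 ± 0.43 for Il1b (0.921; -0.38 without DMSO 6 h replicate C). Limma called 0 probe sets, with 1209 (6.15%) at an unadjusted p under 0.05 and 2 with the GCOS signal at either pseudocount.

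Along the UV response at 6 h, AG825 skin lay closer to sham than DMSO skin did. The mean over 400 UV-responsive genes, signed by direction, went from -0.70 ± 0.09 (SD) after sham to 0.71 ± 0.05 at 6 h in DMSO skin, and from -0.57 ± 0.08 to 0.41 ± 0.15 in AG825 skin. The irradiated arrays of the drugs differed by -0.30 (exact permutation p = 0.0286, the smallest that 70 labelings allow). The response was 0.98 with AG825 against 1.41 with DMSO, or 69.6% of it, a difference of -0.43 ± 0.10 (SE; permutation p = 0.00204 over 4900 labelings). Sham arrays of the drugs differed by 0.13 (exact p = 0.114). All 4 AG825 arrays at 6 h, from 0.27 on replicate A to 0.63 on replicate D, lay below the DMSO arrays, which spanned 0.66 to 0.79. The hair score of these arrays moved with them, at -2.00 ± 1.24 (SD) in DMSO and -0.04 ± 1.28 in AG825 skin at 6 h; with it as a covariate the difference was -0.10 (exact p = 0.229), and without the 3 arrays of lowest percent present it was -0.22 (exact p = 0.2). Too few labelings are left without those 3 arrays for the exact p to reach 0.05, so that p decides nothing. The p became 0.0571 with the GCOS signal (-0.33), with 500 genes per direction (-0.28), and without any 1 of the DMSO 6 h arrays C (-0.30), E (-0.26), F (-0.29) and G (-0.29). At 24 h the drugs differed by -0.06 (exact p = 0.686), with responses of 1.11 in AG825 and 1.31 in DMSO skin, and the interaction was -0.20 ± 0.14 (permutation p = 0.211). Without DMSO 24 h replicate E the 24 h difference was 0.02.

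**Figure D3:**
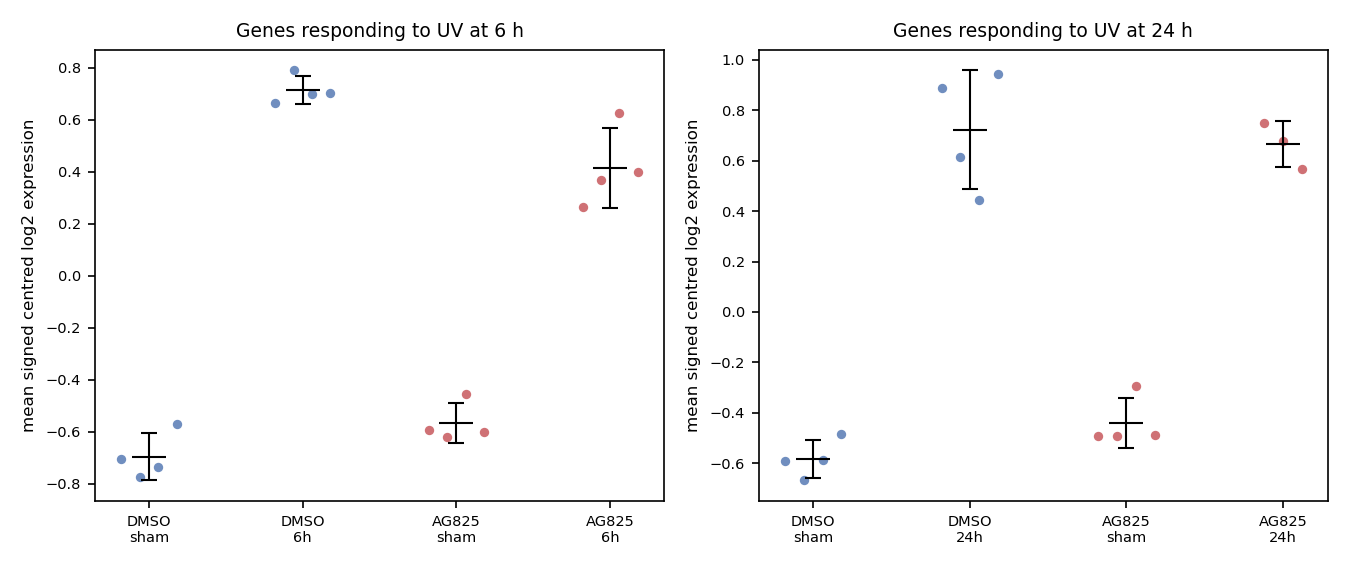
Mean signed centred log2 expression over UV-responsive genes on each sham and UV array of both drugs, at 6 h and at 24 h (DMSO in blue, AG825 in red; points are arrays, black bars the mean ± SD). At 6 h the AG825 arrays lie between 0.27 and 0.63 and the DMSO arrays between 0.66 and 0.79.

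At 24 h after UV, 3 AG825 arrays were compared with 4 DMSO arrays. Cytokine and neutrophil genes had lower values with AG825. Cxcl2 was lower, at -1.81 ± 0.53 (adjusted p = 0.46; -1.04 without AG825 24 h replicate C), as were the chemokine Ccl3 at -1.61 ± 0.35 (0.321), Il1b at -1.14 ± 0.33 (0.46), Trem1, an activating receptor of neutrophils, at -1.25 ± 0.26 (0.264) and Ptgs2 at -0.89 ± 0.34 (0.46). Cholesterol synthesis genes had higher values, Hmgcs1 by 0.70 ± 0.23 and Idi1 by 0.65 ± 0.19. Members that passed adjusted over the list alone were 4 of 23 cytokine genes (mean -0.43), 4 of 11 neutrophil genes (mean -0.58), 3 of 13 cholesterol genes (mean 0.34), 1 of 16 matrix protease genes (mean -0.36), 2 of 20 G1/S genes (mean 0.25), 0 of 20 mitotic genes (mean 0.27) and 0 of 17 interferon genes (mean 0.73). The camera adjusted p at the preset correlation was 3.35e-05 for cytokines, 4.13e-06 for neutrophils, 7.29e-05 for cholesterol, 0.000214 for matrix proteases and 3.4e-08 for interferon, and for each of these 5 lists adjusted p = 0.283 with an estimated correlation. For mitosis it was 0.00018 (adjusted p = 0.645 with an estimated correlation) and for G1/S 0.000287 (adjusted p = 0.43 with an estimated correlation). The other 19 lists were not called. The interferon mean was 0.27 without AG825 24 h replicate C, the cholesterol mean 0.21 without DMSO 24 h replicate E and the cytokine mean -0.28 without DMSO 24 h replicate A. No list passed by exact permutation (lowest p = 0.0857).

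Tmem14c, a mitochondrial membrane protein needed for haem synthesis, was lower with AG825 at -2.21 ± 0.35 (adjusted p = 0.0553), the smallest adjusted p at 24 h. Erbb2 differed by 0.09 ± 0.16 (0.782), Egfr by -0.30 ± 0.14 (0.465), Erbb3 by 0.45 ± 0.23 (0.468) and Erbb4 by -0.02 (0.93). Mki67 differed by 0.73 ± 0.34 (0.46), Cdkn1a by 0.17 (0.662), Krt6a by -0.23 (0.817) and Cyp1a1 by 0.51 ± 0.23 (0.46). Limma called 0 probe sets, with 2087 (10.6%) at an unadjusted p under 0.05. The dChip signal gave 2, either filter 1, array weights 1944 and leaving out DMSO 24 h replicate E 2. The weight of AG825 24 h replicate A was 7.65, against 0.375 to 1.99 on the other arrays. Weighted counts with this group therefore lean on 1 array. Arrays did not overlap for 16.1% of probe sets, where chance gives 5.71%. The array medians did not overlap either, at 7.54 to 7.57 with AG825 and 7.59 to 7.64 with DMSO. The median difference over all probe sets was -0.05, and 0.0118 with the arrays centred on their medians. Such an offset can add to this share and to that of low unadjusted p-values, so neither share is read as a drug effect. The 95% interval lay within ±1 for 94.0% of probe sets.

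The interaction at 24 h called 1 probe set, Tmem14c, at -3.10 ± 0.47 (adjusted p = 0.0364), with 1049 at an unadjusted p under 0.05. The call was lost, with adjusted p between 0.056 and 0.273, without any 1 of 11 arrays (DMSO sham A and B, DMSO 24 h A, B, C and E, AG825 sham B, D and E, AG825 24 h A and C). It was also lost, with 0 probe sets called, with percent present as a covariate, with a fit of only the groups compared, with the GCOS signal at a pseudocount of 1, and without the 3 arrays of lowest percent present; array weights gave 124. Camera called 9 of the 26 lists at the preset correlation and 0 with an estimated one (lowest adjusted p = 0.0598 with an estimated correlation). Cytokine genes had a mean interaction of -0.67 ± 0.23, a smaller rise with AG825, and 4 of 23 passed adjusted over the list alone (camera adjusted p = 2.27e-09, adjusted p = 0.122 with an estimated correlation; permutation p = 0.0122, adjusted 0.125). Il1b had an interaction of -1.90 ± 0.45 (adjusted p = 0.855) and Cxcl2 of -2.89 ± 0.72. Neutrophil genes had a mean of -0.70 ± 0.25, with 6 of 11 adjusted over the list alone (camera adjusted p = 5.65e-08, adjusted p = 0.122 with an estimated correlation; permutation p = 0.0306, adjusted 0.159). Mitotic genes had a mean of 0.61 ± 0.21 (camera adjusted p = 9.02e-13, adjusted p = 0.184 with an estimated correlation; permutation p = 0.0147, adjusted 0.125). Mki67 had an interaction of 1.33 ± 0.46 (0.855), Ptgs2 of -1.20 ± 0.46 (0.855) and Erbb2 of 0.19 (0.887). The high Mki67 value of DMSO sham replicate A raises that of Mki67 here as well. Part of these list interactions lay in the sham arrays. There the AG825 minus DMSO means were 0.24 for cytokine, 0.12 for neutrophil and -0.34 for mitotic genes. Cxcl2 was 6.33 to 7.34 on the AG825 sham arrays and 5.37 to 5.89 on the DMSO sham arrays.

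The response to UV within AG825 skin at 6 h (4 arrays against 4) was led by the same kinds of inflammatory genes. Saa3 rose by 4.11 ± 0.64, Cxcl5 by 3.84 ± 0.31, Cxcl1 by 3.60 ± 0.35, Cxcl2 by 3.35 ± 0.49, Il6 by 3.22 ± 0.45 and Il1b by 2.54 ± 0.30. Ptgs2 rose by 1.72 ± 0.31 (adjusted p = 0.00353), although another probe set for it did not pass. Falls were shallower than the rises, and among the largest were those in Id4, an inhibitor of basic helix-loop-helix factors (-1.76 ± 0.30), Sostdc1, an antagonist of Wnt and BMP signals (-1.51 ± 0.31), and the tight junction gene Cldn23 (-1.45 ± 0.32). Camera called 15 of the 26 lists at the preset correlation and 2 with an estimated one. Cytokine genes rose in 12 of 23 (19 adjusted over the list alone; camera adjusted p = 2.85e-22, adjusted p = 0.00782 with an estimated correlation) and immediate early genes in 6 of 19 (8 adjusted over the list alone; camera adjusted p = 8.86e-08, adjusted p = 0.0137 with an estimated correlation). Macrophage genes rose in 5 of 17 (10 adjusted over the list alone; camera adjusted p = 6.88e-10, adjusted p = 0.206 with an estimated correlation). No hair, mitotic or melanocyte gene passed. The hair list had a mean of -0.97 (camera adjusted p = 0.000183, adjusted p = 0.518 with an estimated correlation), which became -0.38 without AG825 6 h replicate D (camera adjusted p = 0.0898). The mitotic list had a mean of -0.14 (camera adjusted p = 0.0282, adjusted p = 0.83 with an estimated correlation), which became -0.27 without AG825 6 h replicate A; its call was lost without AG825 sham replicate D (-0.01, 0.648) and without AG825 6 h replicate D (-0.04, 0.444) or E (-0.09, 0.158). Mki67 differed by -0.12 ± 0.31 (adjusted p = 0.883), Erbb2 by -0.18 ± 0.15 (0.578), Egfr by 0.07 ± 0.13, Erbb3 by -0.58 ± 0.21 (0.179), Erbb4 by 0.07 (0.734), Cdkn1a by 0.55 ± 0.17 (0.0929), Krt6a by 0.15 (0.898) and Cyp1a1 by -0.09 (0.872). In all, 537 probe sets passed, 290 higher and 247 lower (202 and 113 with the GCOS signal at a pseudocount of 1). Of the 290, 275 were also higher at 6 h in DMSO skin, where chance would give 22.5 if probe sets varied independently. Of the 247, 201 were also lower (26.4 by chance on the same assumption). The count was 258 without AG825 6 h replicate D, 301 without AG825 sham replicate E, 306 without sham replicate C and 351 without sham replicate B, and 280 with percent present as a covariate.

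At 24 h in AG825 skin (3 arrays against 4 sham arrays taken at 6 h), Cxcl5 rose by 4.81 ± 0.34, Saa3 by 4.73 ± 0.70, Cxcl1 by 3.70 ± 0.38 and Il1b by 2.21 ± 0.33. Ptgs2 rose by 1.5 ± 0.34 (adjusted p = 0.0121), a call lost without AG825 24 h replicate A (1.29, adjusted p = 0.106). Tmem14c fell by 2.35 ± 0.35 (adjusted p = 0.000417), and Lce1a2 (-1.67 ± 0.32) and Cd207 (-1.45 ± 0.23) fell as well. Camera called 15 of the 26 lists at the preset correlation and 0 with an estimated one. Macrophage genes rose in 13 of 17 (15 adjusted over the list alone; camera adjusted p = 9.63e-17, adjusted p = 0.0755 with an estimated correlation) and interferon-responsive genes in 10 of 17 (15 adjusted over the list alone; camera adjusted p = 1.86e-14, adjusted p = 0.0755 with an estimated correlation). Cytokine genes rose in 11 of 23 (13 adjusted over the list alone; camera adjusted p = 1.45e-11, adjusted p = 0.0755 with an estimated correlation). Erbb2 differed by -0.48 ± 0.16 (adjusted p = 0.0899), Egfr by -0.15 (0.532), Erbb3 by -0.42 ± 0.23 (0.298), Erbb4 by -0.08 (0.63), Mki67 by 0.34 (0.555), Cdkn1a by 0.35 (0.284), Krt6a by 0.44 (0.576) and Cyp1a1 by -0.12 (0.77). In all, 952 probe sets passed, 659 higher and 293 lower (777 and 197 with the arrays centred on their medians). Of the 659, 498 were also higher at 24 h in DMSO skin (32.2 by chance if probe sets varied independently). Of the 293, 153 were also lower (11.2 by chance on the same assumption). The count was 333 without AG825 24 h replicate A, 568 without B and 620 without C; it was 634, 499, 1670 and 537 without AG825 sham replicates B, C, D and E, and 419 and 352 with the GCOS signal at pseudocounts of 16 and 1.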

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

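The tests with the hair score or percent present as a covariate, those without the arrays of lowest percent present, the contrast of macrophage with other tissue lists and the test of a variant for Tmem14c were chosen after the results had been seen; the comparisons of 24 h with 6 h, and so their splits, were added then too, while the other splits of the arrays, the comparison of probe summaries and the leaving out of single arrays were planned.

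Hair follicle, melanocyte and mitotic genes were lower together at 6 h after UV in DMSO skin, with list differences of -3.17, -1.42 and -0.98. With the hair score as a covariate the mitotic list still differed by -0.7671 ± 0.262 (SE) and the melanocyte list by -0.6922 ± 0.284. A single linear term in a score of hair genes, which itself fell with UV, can leave part of a follicle effect. These remainders therefore cannot exclude follicle content of the skin pieces as the whole cause. Macrophage genes rose by 1.573 ± 0.232 more than the mean of muscle, fibroblast and adipocyte genes. This contrast cannot decide on follicle content, since macrophage genes can rise with inflammation whatever the share of follicle. Muscle, fibroblast and adipocyte lists also had positive means, of 0.71, 0.58 and 0.38, as a smaller share of follicle would give. The count of 3623 probe sets dropped to 305 with the hair score as a covariate. With percent present as a covariate the mitotic list differed by -0.8525 ± 0.19 and the hair list by -2.474 ± 0.69, which argues against array quality as the whole cause. A response of the follicle and its cycling cells to UV may underlie the pattern, as a hypothesis found and tested on the same arrays. A difference in hair cycle between the sampled areas stays open for the hair, melanocyte and mitotic lists alike.

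The UV response along 400 responsive genes differed between the drugs at 6 h, with an interaction of -0.4288, and AG825 skin lay -0.30 from DMSO skin towards sham. Array quality as the whole cause is argued against by the value of -0.2743 ± 0.104 with percent present as a covariate, and a single array by the smallest value with any 1 of the 8 arrays left out, -0.2647. Without the 3 arrays of lowest percent present, 3 of those 8, it was -0.22 (exact p = 0.2). With the hair score as a covariate it was -0.1019 ± 0.096, so that a difference in follicle content between the arrays at 6 h could account for most of it. That score itself fell with UV, so an effect of AG825 on the UV response, which the design names, also stays open, and neither of these was singled out by the tests.

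Tmem14c had an interaction of -3.096 at 24 h, with low values in the 3 irradiated AG825 arrays (7.21, 7.82 and 8.19). The low values are in every probe summary: the interaction was -3.10 with RMA, -3.42 with dChip and -3.227 with GCOS, which argues against the summary as the cause. A candidate explanation is a sequence or expression variant carried by some of these outbred mice, since 2 arrays outside the group, DMSO sham replicates A (8.40) and B (8.67), also lay below the widest gap in the sorted values, 0.762. An effect of AG825 with UV on the gene stays open and had no test of its own.

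Other splits of the arrays were counted for each comparison, as the number that gave as many probe sets as the real one. No other split reached the count for UV against sham in DMSO skin at 6 h (1 of 35 splits, 3623 against at most 381 in another split) or at 24 h (1 of 35, 1714 against 3). This argues against chance, but 1 of 35 is the most that 35 splits can show, and both comparisons use the same sham arrays. The count alone did not argue against chance for UV against sham in AG825 skin at 6 h (2 of 35, 537 against 773) and at 24 h (2 of 35, 952 against 1813). Most higher calls were shared with DMSO skin, measured on separate arrays. At 6 h 275 of 290 were shared (22.5 by chance) and at 24 h 498 of 659 (32.2 by chance), with 0 opposite calls. These figures by chance take probe sets as independent. Genes that vary together could share calls for another reason than UV, so the overlap cannot exclude chance for these counts. Chance was not excluded for 24 h against 6 h in DMSO skin (2 of 35, 9 against 1104). In AG825 skin no other split reached the count for 24 h against 6 h (1 of 35, 45 against 1), but that count was 0 with only the groups compared, 0 with percent present as a covariate and 0 without AG825 24 h replicate A or 6 h replicate A, so nothing is concluded from it. The other counts decide nothing about chance. A real count of 0 is matched by every split, as for AG825 against DMSO after sham (35 of 35, at most 3 in another split), at 6 h (35 of 35, at most 120) and at 24 h (35 of 35, at most 2), and for the interaction at 6 h (100 of 100, at most 6). The interaction at 24 h (1 of 100, 1 against 0) rests on the single call of Tmem14c, which is lost without any 1 of 11 arrays. The split with 120 set AG825 replicates A, B and E with DMSO replicate C against the rest, and the split with 1104 set the 24 h replicates A, B and C with 6 h replicate C against the rest. The splits with 1813 and 773 set AG825 sham replicate D with 24 h replicates A, B and C, and with 6 h replicates A, B and D. These counts point to a structure of the samples that the groups do not describe. The hair score parts the sides of all 4 splits: -0.55 to 1.15 against -3.18 to -1.40 in the split with 120, -0.55 to 0.91 against -3.18 to -1.40 in that with 1104, -0.25 to 0.36 against 1.22 to 1.46 in that with 1813, and -1.83 to 0.52 against 1.15 to 1.46 in that with 773.

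Single arrays far from the other 3 of their group were found in 12 of 185 tests, where chance alone gives about 9.25. AG825 sham replicate E stood out in stress keratins and alarmins (0.727, others -0.94 to -0.744) and in epidermal differentiation (0.95, others 0.34 to 0.432). AG825 6 h replicate A was low in epidermal differentiation (-1.53, others -0.0286 to 0.175). AG825 sham replicate D was high in aryl hydrocarbon receptor targets (0.275, others -0.0365 to -0.0152), in fibroblast matrix (0.287, others -0.413 to -0.31) and in Cyp1a1 (9.51, others 8.98 to 9.06), and low in hair genes (-0.249, others 1.22 to 1.46). DMSO 6 h replicate C had an immediate early score of 0.148 (others 0.239 to 0.254), a heat shock score of 0.132 (others -0.0829 to -0.0486) and a cholesterol score of -0.00165 (others -0.33 to -0.284). DMSO 24 h replicate C had a matrix protease score of 0.252 (others 0.637 to 0.705), and DMSO sham replicate A an Mki67 value of 10.9 (others 9.99 to 10.1).

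The 2981 cross-hybridising probe sets that the log2 table lacks were tested with limma on the dChip signal. Of these, 521 passed for UV against sham in DMSO skin at 6 h (298 higher and 223 lower) and 234 at 24 h (194 higher and 40 lower). In AG825 skin 94 passed at 6 h (75 higher and 19 lower) and 173 at 24 h (146 higher and 27 lower). At 24 h, 1 was lower with AG825 than with DMSO and 1 had a negative interaction. Limma called 0 of 2981 for AG825 against DMSO after sham and at 6 h and for the interaction at 6 h, with 38, 206 and 202 at an unadjusted p under 0.05.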

How the results depend on the processing

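The hair score covariate, the percent-present covariate, the setting without the 3 arrays of lowest percent present, the permutation of list scores and the 24 h against 6 h comparisons were chosen after the data had been seen; the other alternatives were planned. UV against sham in DMSO skin at 6 h (3623 probe sets) gave 2277 with GCOS at a pseudocount of 1, 5495 with array weights, 2411 with the replicate letter as a block, 305 with the hair score, 2068 with percent present and 1868 without the arrays of lowest percent present; leave-one-out gave 2506 to 4164. At 24 h (1714) it gave 975 with GCOS at a pseudocount of 1, 2802 with array weights and 1133 with the hair score; leave-one-out gave 975 to 1934. AG825 against DMSO after sham gave 0 throughout. At 6 h (0) it gave 2 and 4 with GCOS at pseudocounts of 16 and 1, 1 without the arrays of lowest percent present, and 0 to 21 leaving 1 array out. At 24 h (0) it gave 2 with dChip, 1 without the dimmest probe sets, 1 with the detection filter, 1944 with array weights and 0 to 2 leaving 1 array out. The weight of AG825 24 h replicate A was 7.65, against 0.375 to 1.99 on the other arrays, so every weighted count with that group leans on 1 array. UV in AG825 skin at 6 h (537) gave 315 with GCOS at a pseudocount of 1, 1022 with array weights, 280 with percent present, 241 with only the groups compared and 258 to 505 leaving 1 array out. At 24 h (952) it gave 625 with dChip, 419 and 352 with GCOS, 9029 with array weights and 333 to 1670 leaving 1 array out. The interaction at 6 h (0) gave 2 and 2 with GCOS, 1 with the block, and 0 to 0 leaving 1 array out. At 24 h (1) it gave 0 with GCOS at a pseudocount of 1, 0 with the block, 0 with percent present, 0 without the arrays of lowest percent present, 0 with only the groups compared, 124 with array weights and 0 to 1 leaving 1 array out. For 24 h against 6 h in DMSO skin (9) the counts were 34 with dChip, 17 with GCOS at a pseudocount of 1, 43 without the dimmest probe sets, 51 with the detection filter, 720 with array weights, 0 with the block, 0 with the hair score, 0 with percent present, 1 with only the groups compared and 0 to 203 leaving 1 array out. In AG825 skin (45) they were 16 with dChip, 3 and 8 with GCOS, 26 with trend and robust moderation, 3543 with array weights, 251 with the block, 227 with the hair score, 0 with percent present, 8 without the arrays of lowest percent present, 0 with only the groups compared and 0 to 89 leaving 1 array out. The AG825 effect along the UV response at 6 h (-0.30, p = 0.0286) was -0.33 with GCOS (p = 0.0571), -0.28 with 500 genes per direction (p = 0.0571), -0.10 with the hair score (p = 0.229), -0.22 without the arrays of lowest percent present (p = 0.2) and -0.35 to -0.26 leaving 1 array out; at 24 h (-0.06) it was -0.15 to 0.018, the latter without DMSO 24 h replicate E. These p-values are from exact permutation. With another summary or centring, the share of higher calls moved by more than 10 points from 42.1% to 53.2% with dChip (UV in DMSO at 6 h), from 56.1% to 73.9% with dChip and 69.6% with GCOS at a pseudocount of 1 (24 h), from 54.0% to 64.1% with GCOS at a pseudocount of 1 (AG825 at 6 h), from 69.2% to 79.8% with median centring (AG825 at 24 h), from 55.6% to 81.8% and 82.4% with GCOS and 37.5% with median centring (24 h against 6 h in DMSO), and from 71.1% to 56.2% with dChip, 25% with GCOS at a pseudocount of 1 and 87.5% with median centring (in AG825). Under the other settings it moved as far for UV in DMSO at 6 h with the hair score (54.8%), for AG825 at 6 h with percent present (67.5%) and without AG825 sham replicate D (64.9%) or 6 h replicate A (65.5%), and for AG825 at 24 h with array weights (39.1%) and without 24 h replicate A (86.5%). For the interaction at 24 h it went from 0% of 1 call to 50% of 124 with array weights. For 24 h against 6 h in DMSO it was 1 of 7 calls without the arrays of lowest percent present, 0% of 1 call with only the groups compared, 67.0%, 66.7% and 67.7% without 6 h replicates C, E and F, and 75% without 24 h replicate A. In AG825 it was 83.7% with the detection filter, 39.9% with array weights, 89.2% with the block, 57.3%, 83.9% and 33.3% without 6 h replicates B, D and E, and 100% of 1 call without 24 h replicate B or C. As for the block, arrays of different groups that share a replicate letter had residuals correlated at a mean r of 0.172 over 35 pairs (-0.228 to 0.672, 21 over 0.1), against -0.031 for different letters, and 10 of 21 arrays correlated best with their own letter. Arrays of the same letter were thus more alike on average, and a batch or animal shared by a letter cannot be excluded. Not every pair was over 0.1, so the letters were not taken as pairs in the main fit, and what they mark stays unknown. With the block the interferon list at 6 h was -0.12 for AG825 against DMSO (camera adjusted p = 0.438) and -0.23 for the interaction (0.132), where it had been -0.63 and -0.75; the interaction at 6 h also had no call with it for Langerhans and T cells (0.148) and mast cells (0.0605). The direction turned for stress keratins in AG825 against DMSO after sham with the block (-0.0759) and leaving 1 array out (-0.218 without DMSO sham replicate A and -0.133 without AG825 sham replicate E, up to 0.739), for stress keratins (0.061) and epidermal differentiation (0.0102) in the interaction at 6 h with the block, for hair genes after sham without AG825 sham replicate D (0.146, others down to -0.425), for muscle genes at 6 h without AG825 6 h replicate E (0.0604), and for Cd4 in UV against sham in DMSO skin at 6 h with dChip (-1.24). Of 4082 repeats for gene lists 3387 kept direction and side of the threshold, 377 lost the call and 109 gained one. In 202 the sign changed with no call in either setting, and 7 turned from a call with the main setting. For the 16933 repeats of named genes these numbers were 15597, 788, 138, 409 and 1. The turns listed above are only those from a call. The cause was not tested in any of these, except that leaving out arrays leaves fewer samples. Signal over background limits the genes called absent, and leaving out the arrays of lowest percent present was not run for the 24 h drug effect along the UV response, since none of them is in it.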

Other observations

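The comparisons of 24 h with 6 h after UV within each drug group were chosen after the data had been seen, as were the exact permutation tests of list scores.

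Between 6 h and 24 h in DMSO skin (4 arrays each), Cxcr4, a chemokine receptor of leukocytes, was 1.22 ± 0.17 higher (log2 difference ± SE, adjusted p = 0.00812) and the interferon-induced chemokine Cxcl10 lower, at -2.16 ± 0.40 (adjusted p = 0.0497), as was the small heat shock gene Hspb1, at -0.54 ± 0.09 (adjusted p = 0.0205). Each of these calls was lost without DMSO 24 h replicate B (adjusted p = 0.0637, 0.215 and 0.132), that of Cxcl10 also without DMSO 6 h replicate E (0.125) or G (0.119) or DMSO 24 h replicate A (0.11), and that of Hspb1 also without DMSO 6 h replicate E (0.102). Adjusted over the list alone, 16 of 20 mitotic genes and 13 of 18 hair genes were higher at 24 h, with means of 0.54 and 1.89, and 11 of 17 interferon genes were lower, with a mean of -0.79. Their camera adjusted p-values were 4.62e-13, 5.22e-12 and 1.52e-09, and for each of these lists adjusted p = 0.197 with an estimated correlation; the permutation p was 0.0857, 0.0857 and 0.0286. In all 9 probe sets passed, 5 higher and 4 lower (9 and 2 with the GCOS signal at a pseudocount of 16, 14 and 3 at 1, and 3 and 5 with the arrays centred on their medians). None passed with the hair score or with percent present as a covariate, and 1 with a fit of only the groups compared. For 5.57% of probe sets there was no overlap between times, where chance gives 2.86%. Leaving out 1 array moved the count of 9 to 0 without DMSO 24 h replicate B, 4 without A, 17 without C and 80 without E, and to 203, 3 and 31 without DMSO 6 h replicates C, E and F.

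In AG825 skin (3 arrays at 24 h and 4 at 6 h), Cxcr4 was 1.05 ± 0.18 higher at 24 h (adjusted p = 0.034) in these arrays. Hspb1 was lower, at -0.63 ± 0.09 (adjusted p = 0.0185), and the Langerhans cell marker Cd207 lower, at -1.21 ± 0.23 (adjusted p = 0.0391). The calls of Cxcr4, Hspb1 and Cd207 were each lost without AG825 24 h replicate A (adjusted p = 0.109, 0.0778 and 0.207), B (0.0744, 0.0671 and 0.0744) or C (0.0902, 0.051 and 0.121) or AG825 6 h replicate A (0.0712, 0.0712 and 0.0785), that of Cxcr4 also without 6 h replicate E (0.0691) and that of Cd207 without 6 h replicate D (0.0522). Of 15 circadian clock genes none passed over all probe sets, and 4 were higher and 3 lower adjusted over the list alone (mean 0.13, median -0.02, camera adjusted p = 0.538); the clock output gene Dbp was 0.91 ± 0.22 higher (0.0045 adjusted over the list alone). In all 45 probe sets passed, 32 higher and 13 lower (9 and 7 with the dChip signal, 2 and 6 with the GCOS signal at a pseudocount of 1, and 56 and 8 with the arrays centred on their medians). None passed with percent present as a covariate or with a fit of only the groups compared. In this comparison 26.2% of probe sets had no overlap between times, where chance gives 5.71%. Array medians were 7.54 to 7.57 at 24 h and 7.59 to 7.63 at 6 h. The median difference over all probe sets was -0.0759, and -0.0222 with the arrays centred on their medians, so an offset between the groups can add to this share. The count of 45 was 0 without AG825 24 h replicate A, 1 without B and 1 without C, and 0, 89 and 6 without AG825 6 h replicates A, B and E.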
